A study of Mus musculus with 16 samples.

How the data were processed

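The samples were 16 polyA-selected, paired-end RNA libraries of mouse bone-marrow-derived macrophages, in 4 groups of 4 set by dish coating and antibody, grouped by the coating and treatment in the labels. Bone marrow cells were held for 24 h in 15% serum with 12 ng/ml CSF-1, then for 48 h with 120 ng/ml CSF-1, per the labels' protocols. RNA was extracted with TRIzol and sequenced on a NovaSeq X Plus, per the labels' protocols.

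The authors deposited a table of whole-number counts per gene and library for 54532 genes, with gene positions, biotypes and lengths, and a table of FPKM for the same genes and libraries. HISAT2, StringTie and featureCounts and the builds mm10 and GRCm38.p6 are named in the submitters' processing notes. The role and version of each tool, the counting options, the strand setting and the handling of reads that match several genes are not given in the sources used here. The deposited FPKM equalled each count divided by gene length and by 1 constant per library, and that constant was 0.989 to 1.04 times the library's total count. Of the genes in the deposited counts, 25574 had no count in any library and 103 gene symbols occurred more than once, so genes were followed by their identifiers. Coordinates are those of the deposited tables, on GRCm38.

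The counts were analysed as deposited with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and Python 3.11.15 with matplotlib 3.10.9 was used for figures. Genes were kept by filterByExpr with default settings (minimum count 10, which is 0.357 CPM at the lowest total), which left 15469 genes, 12343 of them protein-coding, with 99.9% of all counts. TMM factors were applied, and a model with 1 mean per group was fitted to all 16 libraries with the robust quasi-likelihood method. The comparisons were anti-ITGAV against IgG on each coating, fibronectin against uncoated under each antibody, and the coating by antibody interaction. Each used edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The CPM values use TMM-scaled totals. Log2 changes are edgeR's and their SE comes from the same fit.

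Gene lists for pathways, the macrophage itself, other cell types and RNA quality (37 lists, 751 symbols, all of them found among the genes) were written before the data were examined, as were the tests, the other settings to be tried and the rule for named genes. Of these, 36 lists had at least 3 tested members and were tested with camera at its preset correlation of 0.01, adjusted over the lists within a comparison. Counts of members are given over all genes tested and adjusted over the list alone.

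For anti-ITGAV on each coating and for fibronectin under IgG, the rule named the 12 higher and 12 lower genes with the largest absolute log2 change. They had to be protein-coding with an adjusted p under 0.05, a mean of at least 1 CPM over the 16 libraries, and no overlap between the libraries of the groups compared. For fibronectin under anti-ITGAV and the interaction the first 6 in each direction were taken, without the overlap condition for the interaction. Itgav, Itgb1, Itgb3, Itgb5, Itgb6, Itgb8 and Fn1 were always named, and so were up to 4 members with the smallest adjusted p of each list described. Integrin, matrix, lipid, alternative activation and macrophage identity lists are described for fibronectin also where camera did not pass, a choice made after their values were seen.

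The settings fixed in advance were DESeq2 1.42.0, other scaling factors, no low-count filter or 1 CPM in 4 libraries, the 8 libraries of a comparison alone, the replicate number as a block, a test against a 1.5-fold change, and leaving out each library in turn. Limma was also run on log2(FPKM + 1) and log2(FPKM + 0.1), for 11324 genes with an FPKM of at least 1 in 4 libraries and without that filter. Lists were also tested with an estimated correlation and with fry. Voom with quality weights, a per-library GC offset, and fits without the library that stood apart were added after the data were seen. The GC offset was a smooth trend of log2 CPM (prior count 2) on transcript GC content, which was known for 15457 of the tested genes.

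Replicates were compared before they were averaged. The chi-square over its degrees of freedom of each pair within a group lay between 5.25 and 197, so no pair was a library deposited again. The analysis was tested on simulated counts of 15469 genes with 200 changed, each gene drawn independently. Trends that genes share within a library, such as that with GC content, were not simulated, so the rates may be worse in the real data. For fibronectin under IgG, edgeR recovered 47.8% of changes of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold, with 7.74% false calls. For the antibody it recovered 86.6% of 2-fold changes on uncoated dishes and 82.1% on fibronectin, with 4.97% and 5.26% false calls. For fibronectin under anti-ITGAV it recovered 92.5% of 2-fold changes with 4.32% false calls, and for the interaction 55.2% with 3.77%. DESeq2 gave 15.5% false calls for the antibody on uncoated dishes and 19.2% for fibronectin under IgG.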

Results

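RNA was sequenced from macrophages grown out of tibial bone marrow of wild-type C57BL/6 mice with CSF-1, the growth factor on which macrophage differentiation depends. The adherent cells were passaged once, onto dishes coated with fibronectin (10 µg/ml), a matrix glycoprotein that integrins bind, or onto normal culture dishes. They were then kept for 24 h with an IgG antibody or with an antibody that neutralizes ITGAV, the αV integrin subunit (10 µg/ml each). The series concerns αV integrin and the state of macrophages in the heart after infarction. The 16 libraries formed 4 groups of 4, called here uncoated_IgG, uncoated_antiITGAV, fibronectin_IgG and fibronectin_antiITGAV. Total counts per library, rounded to 6 digits, ranged from 27995000 to 43413600. A count of 0 in a library allows up to 3 counts, or 0.0691 to 0.107 CPM (counts scaled by the library's total) depending on the library, a limit that covers counting error only. The 15469 genes tested had a median standard error (SE) of 0.19 on the log2 scale in each comparison of a pair of groups. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

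Macrophage genes were abundant in these cultures, and the lists of markers of other blood and stromal cells had lower medians. The 15 macrophage identity genes had a median of 354 CPM, with the lysozyme gene Lyz2 at 23421 CPM. The 16 neutrophil markers had a median of 10.2 CPM (highest S100a9, 95.3 CPM), the 8 mast cell and basophil markers 1.45 CPM (highest Prss34, 11.1 CPM) and the 7 B lymphocyte markers 0.494 CPM (highest Ighm, 50.1 CPM). The 11 fibroblast markers had a median of 0.645 CPM and the 3 T and NK lymphocyte markers 0.263 CPM. Single markers were abundant: the 8 monocyte markers had a median of 10.4 CPM with Ccr2 at 159.6 CPM, and the 7 megakaryocyte and platelet markers 2.97 CPM with Pf4 at 524.7 CPM, above the macrophage median. The library fibronectin_antiITGAV 3 stood apart from the rest. Mitochondrial genes took 3.67% of its counts, against 1.30 to 1.60% in the other 15 libraries, and its mean Pearson correlation with the others across genes was 0.965, against 0.976 to 0.983. The deviation of a library's log2 CPM from the mean of all libraries followed the GC content of the transcripts in many libraries. Spearman's rho across genes, which are not independent replicates, was -0.75 in fibronectin_antiITGAV 3 and -0.35 to 0.61 in the others. The group means of rho were -0.07 ± 0.38 (SD, n = 4) in uncoated_IgG, 0.25 ± 0.36 in uncoated_antiITGAV, 0.12 ± 0.48 in fibronectin_IgG and -0.14 ± 0.47 in fibronectin_antiITGAV.

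**Figure D1:**
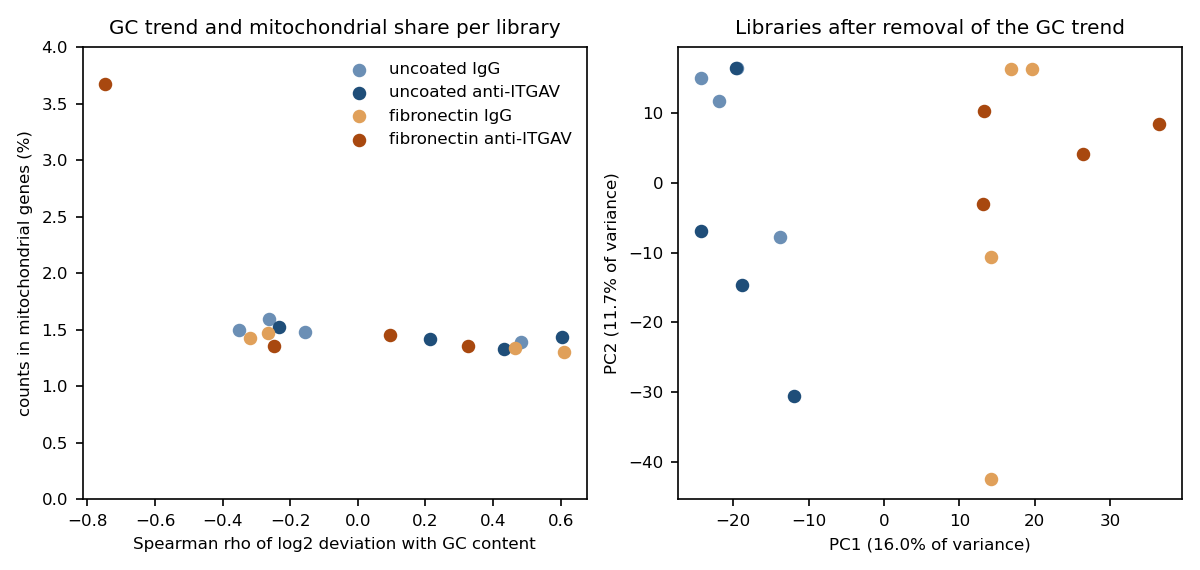
Left, Spearman's rho between each library's log2 deviation and transcript GC content (x axis) against its mitochondrial share of counts in percent (y axis), 1 point per library; fibronectin_antiITGAV 3 lies at -0.75 and 3.67%. Right, the first and second principal components of log2 CPM after each library's GC trend was removed (15.995% and 11.7% of the variance), with the fibronectin libraries on one side of the first component and the uncoated ones on the other.

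Itgav, which encodes the antibody's target (chromosome 2, 83724397 to 83806916, plus strand, GRCm38), was not distinguishable between antibodies on either coating. It stood at 95.7 ± 14.7 CPM (SD, n = 4) with anti-ITGAV and 100 ± 11.8 CPM with IgG on uncoated dishes, a log2 change of -0.07 ± 0.16 (SE). On fibronectin it stood at 171 ± 13.9 CPM with anti-ITGAV and 144 ± 38.7 CPM with IgG, a log2 change of 0.25 ± 0.16 (SE, edgeR adjusted p = 0.721). The antibody binds the protein, so Itgav RNA is no check of the labels. Of the β subunits that pair with αV, Itgb1 (chromosome 8, 128685654 to 128733200), Itgb3 (chromosome 11, 104608000 to 104670476) and Itgb5 (chromosome 16, 33829665 to 33949338) passed the test in no comparison, with log2 changes for the antibody of -0.05, 0.36 and 0.02 on uncoated dishes and 0.17, -0.08 and -0.21 on fibronectin. Itgb6 and Itgb8 were not among the genes tested. Fn1, which encodes fibronectin itself (chromosome 1, 71585520 to 71653200, minus strand), did not pass for the antibody either, at 0.07 on uncoated dishes and -0.19 on fibronectin (edgeR adjusted p = 0.721 for the latter).

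The first question was what neutralizing αV did to macrophages on normal dishes. Myo1e, an unconventional myosin of the actin cortex, rose to 133 ± 10.2 CPM with anti-ITGAV from 84.8 ± 8.64 CPM with IgG (SD, n = 4), a log2 change of 0.65 ± 0.08 (SE, edgeR adjusted p = 0.00869). Fos, an immediate early transcription factor, rose to 30.7 ± 4.93 from 18.4 ± 1.13 CPM, a log2 change of 0.74 ± 0.11 (SE, edgeR adjusted p = 0.0264). These were the 2 genes called. With the 8 uncoated libraries fitted alone edgeR called 3 genes, among them Myo1e (adjusted p = 0.0385) but not Fos (0.107). Myo1e was not called without uncoated_IgG 1 or 2 or uncoated_antiITGAV 1 or 3 (edgeR adjusted p = 0.0541 to 0.114), and Fos without any 1 of the 8 libraries except uncoated_antiITGAV 4 (0.0704 to 0.247). Fos was the 1 member called of a list of 27 immediate early genes, which stood higher as a group (camera adjusted p = 1.16e-11). Their median log2 change was 0.25, and 10 members were higher when adjusted over the list alone. Its call held with an estimated correlation (adjusted p = 0.0368), and Egr1, Dusp5 and Egr2 had log2 changes of 1.33, 0.83 and 0.59 (edgeR adjusted p = 0.495 each). Neutrophil markers stood lower as a group on the same dishes, with a median of -0.22 over 16 genes (camera adjusted p = 1.19e-05). Singly, none of these passed edgeR's test over all genes, and 4 were lower when adjusted over the list alone. Ltf and Lcn2, secretory proteins of neutrophil granules, had log2 changes of -0.54 and -0.45 there (edgeR adjusted p = 0.321 and 0.495). The 8 mast cell and basophil markers also stood lower, with a median of -0.37 and 1 lower when adjusted over the list alone (camera adjusted p = 0.000509), and the calls of both marker lists held with an estimated correlation (adjusted p = 0.0368 each).

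Smaller upward shifts of 8 further lists on uncoated dishes did not hold with an estimated correlation. Focal adhesion and actin genes (29 genes, median 0.10) and glycolysis and hypoxia genes (26 genes, median 0.10) each had a camera adjusted p of 0.000957, and an adjusted p = 0.433 with an estimated correlation. Osteoclast and multinucleation genes (16 genes, median 0.08, camera adjusted p = 0.00285) had an adjusted p = 0.254 with an estimated correlation. Their fusion gene Dcstamp had a log2 change of 1.15 (edgeR adjusted p = 0.386). Lysosome genes (median 0.09, camera adjusted p = 0.0032) and NF-kB targets (median 0.18, camera adjusted p = 0.02) had an adjusted p = 0.433 with an estimated correlation. Genes of LXR and lipid handling (median 0.10, camera adjusted p = 0.0039) had an adjusted p = 0.402 with an estimated correlation. Macrophage identity genes (median 0.07, camera adjusted p = 0.0103) had an adjusted p = 0.413 with an estimated correlation, and type I interferon genes (median 0.08, camera adjusted p = 0.02) had an adjusted p = 0.601 with an estimated correlation. In these 8 lists edgeR called 0 genes over all genes tested; in the whole comparison 470 genes had an unadjusted p under 0.05 and DESeq2 called 16. Adjusted over the list alone, 1 NF-kB target was lower, 1 osteoclast gene and 1 macrophage identity gene were higher, and the other 5 lists had none. The NF-kB call ended without uncoated_IgG 3 or 4 or uncoated_antiITGAV 1 or 2, and the interferon call without uncoated_IgG 3 or 4 or uncoated_antiITGAV 2 or 4 (camera adjusted p = 0.0523 to 0.225 and 0.0867 to 0.633).

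The same antibody on fibronectin lowered Ltf and Lcn2. Ltf, which encodes lactotransferrin (chromosome 9, 111019271 to 111042767), fell to 30.9 ± 1.41 CPM with anti-ITGAV from 62.0 ± 10.98 CPM with IgG (SD, n = 4), a log2 change of -1.002 ± 0.111 (SE, edgeR adjusted p = 0.000992). Lcn2, which encodes the iron-chelating protein lipocalin-2 (chromosome 2, 32384633 to 32388252), fell to 13.9 ± 0.401 from 24.6 ± 3.54 CPM, a log2 change of -0.83 ± 0.11 (SE, edgeR adjusted p = 0.00436). Both belong to the list of 16 neutrophil markers, whose median was -0.59 (camera adjusted p = 1.63e-18, and adjusted p = 0.000951 with an estimated correlation). Adjusted over the list alone, 9 were lower and 1 higher. Camp and S100a9 of that list had log2 changes of -1.01 and -0.62 (edgeR adjusted p = 0.131 each). Lcn2 was not called without fibronectin_antiITGAV 1 (edgeR adjusted p = 0.055), and 5 genes were called without fibronectin_antiITGAV 3. With the 8 fibronectin libraries fitted alone edgeR called 0 genes, with 276 at an unadjusted p under 0.05, and DESeq2 on all libraries called 16.

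**Figure D2:**
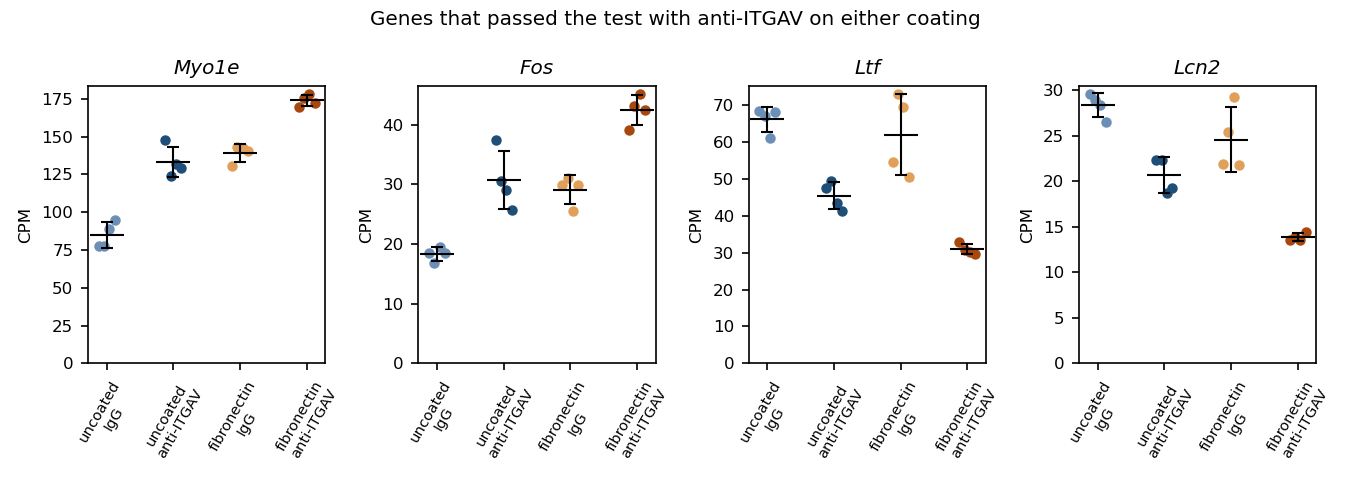
CPM of the genes called for anti-ITGAV on either coating, 1 point per library in each of the 4 groups, with the bar at the group mean and the error bar at ± 1 SD (n = 4). Myo1e and Fos stand higher with the antibody on uncoated dishes, and Ltf and Lcn2 stand lower with it on fibronectin.

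A further 4 lists passed camera for the antibody on fibronectin, and none held with an estimated correlation. Ribosomal protein genes stood lower (26 genes, median -0.19, camera adjusted p = 5.07e-06) and mitochondrial transcripts higher (12 genes, median 0.53, camera adjusted p = 3.16e-05), each with an adjusted p = 0.956 with an estimated correlation. Without fibronectin_antiITGAV 3 the mitochondrial median was -0.01 (camera adjusted p = 0.98). Type I interferon genes stood higher (32 genes, median 0.14, camera adjusted p = 0.0367), with an adjusted p = 0.956 with an estimated correlation. Mast cell and basophil markers stood lower (8 genes, median -0.13, camera adjusted p = 0.0372), with an adjusted p = 0.426 with an estimated correlation. In these 4 lists edgeR called 0 genes over all genes tested, and adjusted over the list alone 1 mast cell gene was lower. In the whole comparison 720 genes had an unadjusted p under 0.05. The interferon call ended without fibronectin_IgG 3 or 4 or fibronectin_antiITGAV 1 or 2, and the mast cell call without fibronectin_IgG 1 or 3 or fibronectin_antiITGAV 2 or 4 (camera adjusted p = 0.0503 to 0.577 and 0.0585 to 0.332).

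A coating by antibody interaction asks whether αV neutralization acted differently on the coatings. For no gene did the interaction pass: edgeR called 0 genes with a smallest adjusted p of 0.646, 614 genes had an unadjusted p under 0.05, and DESeq2 called 1. Myo1e and Fos had log2 changes of 0.32 and 0.55 for the antibody on fibronectin, and Ltf and Lcn2 had -0.54 and -0.45 on uncoated dishes, the same sign on both coatings for each of these 4 genes. Across the 15469 genes tested, the antibody's log2 changes on the coatings had a Pearson correlation of -0.0509, and -0.43 over the 8598 genes with at least 10 CPM, values that are across genes and not across independent replicates. With each library's GC trend taken out, a step added after the data were seen, the correlation was 0.0626 over all genes and 0.0717 over the 8598, so the negative value did not hold. The median SE of the interaction was 0.26, and in simulated data 55.2% of 2-fold interactions were recovered.

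Macrophages on fibronectin had more Ccl2, Ccl7 and Ch25h RNA than those on uncoated dishes, and less Thbs1 RNA. Under IgG, 586 genes differed between fibronectin and uncoated dishes, of which 367 rose and 219 fell, and 86 changed by at least 2-fold (59 up, 27 down; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Ch25h, the enzyme that makes 25-hydroxycholesterol (chromosome 19, 34473786 to 34475135), rose most among the named genes, to 4.57 ± 0.605 from 0.53 ± 0.138 CPM (SD, n = 4), a log2 change of 3.08 ± 0.29 (SE, edgeR adjusted p = 2.03e-05). The monocyte chemoattractants Ccl2 and Ccl7, neighbours on chromosome 11, rose to 141 ± 39.7 from 41.6 ± 2.97 CPM and to 83.8 ± 22.3 from 24.0 ± 1.57 CPM, with log2 changes of 1.76 ± 0.17 and 1.80 ± 0.20 (SE, edgeR adjusted p = 2.41e-05 and 8.91e-05). The other large rises were in Slco4a1 (2.37), Cspg4 (1.91), the ephrin receptor gene Epha2 (1.91), Id1 (1.70), Map1a (1.63), Gpr84 (1.52), Chst11 (1.505), Fam20a (1.49) and Myc (1.46 on the log2 scale). Thbs1, which encodes the matrix protein thrombospondin-1 (chromosome 2, 118111876 to 118127133), fell to 103 ± 6.33 from 238 ± 20.1 CPM, a log2 change of -1.21 ± 0.10 (SE, edgeR adjusted p = 2.03e-05). Spic, a transcription factor of iron-recycling macrophages, fell to 0.922 ± 0.29 from 3.26 ± 0.52 CPM, a log2 change of -1.81 ± 0.31 (SE, edgeR adjusted p = 0.00312). The other large falls were in Ms4a4a (-1.40), Slc16a9 (-1.35), Il4 (-1.31), Cd4 (-1.30), Samd4 (-1.24), Gprc5c (-1.24), Gpr34 (-1.22), Ctla2a (-1.20), Pik3ip1 (-1.14) and Gria3 (-1.12 on the log2 scale). Leaving out uncoated_IgG 1, 2 or 3 or fibronectin_IgG 3 or 4 left 253, 273, 282, 279 and 320 genes, and leaving out fibronectin_antiITGAV 3, which enters through the shared estimate of spread, gave 1325. Il4 and Gpr34 were not called without fibronectin_IgG 3, nor Pik3ip1 without uncoated_IgG 1, nor Gria3 without any 1 of 6 libraries, uncoated_IgG 1, 2 or 3 or fibronectin_IgG 2, 3 or 4 (edgeR adjusted p = 0.0574, 0.0506, 0.0507 and 0.0799 to 0.116).

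**Figure D3:**
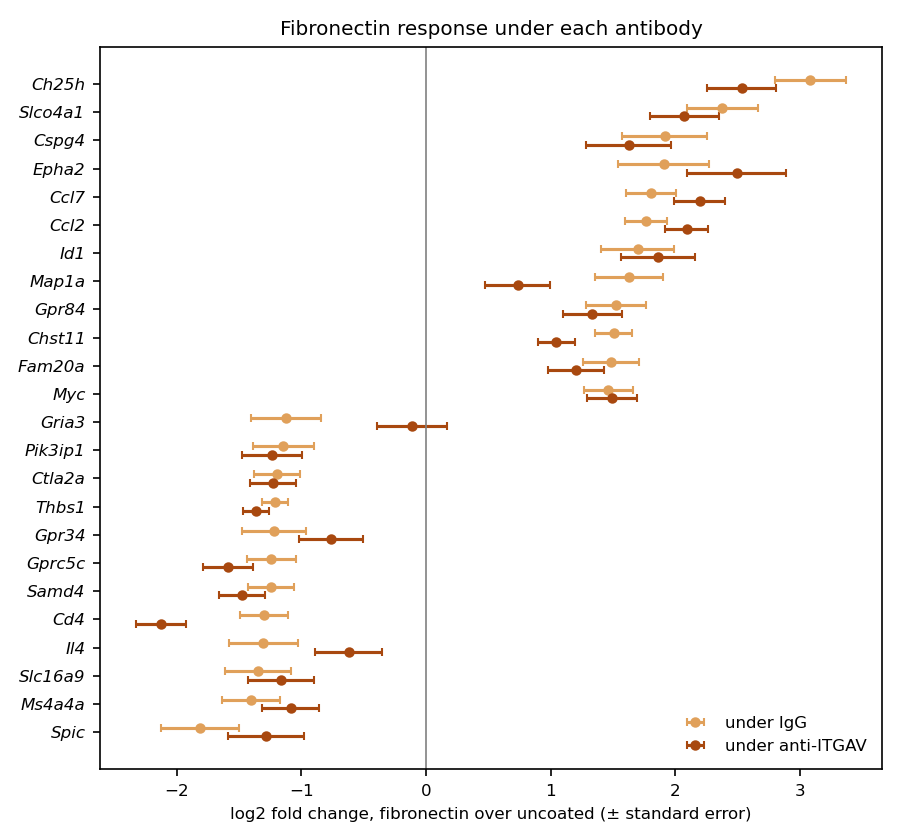
Log2 change on fibronectin against uncoated dishes (x axis, point with ± 1 SE) of the 24 genes that the naming rule gave by size of change for fibronectin under IgG, 12 higher and 12 lower (protein-coding, a mean of at least 1 CPM and no overlap between the groups), shown for both antibodies. All 24 have the same sign under IgG and under anti-ITGAV.

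The lists of NF-kB targets, immediate early genes, and glycolysis and hypoxia genes passed camera upward on fibronectin under IgG. Of 26 NF-kB targets 7 rose (9 higher and 1 lower when adjusted over the list alone), with a median log2 change of 0.30, and Ccl2 and Ccl7 were joined by Ccl4 (1.01) and Tnf (1.26). The list's camera adjusted p was 7.49e-09, and its adjusted p = 0.0578 with an estimated correlation. Of 27 immediate early genes 8 rose (11 when adjusted over the list alone, median 0.30, camera adjusted p = 1.00e-09), among them Myc and the MAP kinase feedback genes Dusp4 (1.33), Dusp6 (0.86) and Spry2 (0.83), with an adjusted p = 0.0578 with an estimated correlation. Of 26 glycolysis and hypoxia genes 7 rose (17 when adjusted over the list alone, median 0.34, camera adjusted p = 7.00e-11), among them the glucose transporter gene Slc2a1 (0.87), Pfkp (0.48) and Ankrd37 (1.03), with an adjusted p = 0.0935 with an estimated correlation. Type I interferon genes did not pass as a group (32 genes, median -0.06, camera adjusted p = 0.0744). Of 16 unfolded protein response genes 2 rose (4 when adjusted over the list alone, median 0.18, camera adjusted p = 0.00374), and of 22 ATF4 targets 2 rose (5 when adjusted over the list alone, median 0.22, camera adjusted p = 0.0168). These 2 lists had an adjusted p = 0.213 and an adjusted p = 0.322 with an estimated correlation. The ATF4 call ended without fibronectin_IgG 2 (camera adjusted p = 0.0932).

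The lists of proteases, TGF-β genes, focal adhesion genes and osteoclast genes also passed camera upward on fibronectin under IgG, and none of these 4 held with an estimated correlation. Plau, the urokinase gene, rose to 328 ± 37.5 from 124 ± 23.7 CPM (SD, n = 4, log2 1.40), its receptor gene Plaur by 1.12 and the macrophage elastase gene Mmp12 by 0.91, within a list of 21 proteases and inhibitors of which 4 rose (5 higher and 2 lower when adjusted over the list alone, median 0.10). Its camera adjusted p was 0.00236, and its adjusted p = 0.0514 with an estimated correlation. Of 28 genes of the TGF-β pathway 4 rose (6 when adjusted over the list alone, median 0.14, camera adjusted p = 0.000603), led by the BMP target Id1, with an adjusted p = 0.0704 with an estimated correlation. Of 29 focal adhesion and actin genes 4 rose (8 higher and 1 lower when adjusted over the list alone, median 0.25, camera adjusted p = 0.000146), led by the kinase gene Ptk2b (0.45), with an adjusted p = 0.266 with an estimated correlation. Of 16 osteoclast and multinucleation genes 3 rose (3 when adjusted over the list alone, median 0.20, camera adjusted p = 0.00175), among them the fusion gene Dcstamp (1.46) and the RANK gene Tnfrsf11a (0.49), with an adjusted p = 0.0967 with an estimated correlation. The integrin list of 18 genes did not pass as a group (median 0.01, camera adjusted p = 0.0744), but Itgax, the CD11c gene, rose to 38.3 ± 3.43 from 16.7 ± 2.66 CPM (SD, n = 4), a log2 change of 1.19 ± 0.12 (SE, edgeR adjusted p = 2.41e-05). Itgav had a log2 change of 0.52 ± 0.16 (SE) and did not pass (edgeR adjusted p = 0.0818). Itga5, the α subunit of the classical fibronectin receptor, rose by 0.60 (edgeR adjusted p = 0.0475), a call that ended without any 1 of the 8 libraries compared (adjusted p = 0.0574 to 0.171).

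Matrix, lipid and activation genes moved in both directions on fibronectin under IgG. Of 28 extracellular matrix genes 3 rose and 3 fell (5 and 5 when adjusted over the list alone, median -0.18, camera adjusted p = 0.292). Fn1 rose to 513 ± 20.2 from 325 ± 50.3 CPM (SD, n = 4), a log2 change of 0.66 ± 0.11 (SE, edgeR adjusted p = 0.00312), while Thbs1 fell. Of 22 alternative activation genes 2 rose and 1 fell (4 and 1 when adjusted over the list alone, median -0.22, camera adjusted p = 0.691). Among them the arginase gene Arg1 rose to 221 ± 2.59 from 85.0 ± 21.3 CPM (log2 1.38, edgeR adjusted p = 0.000133) and the lectin gene Clec10a fell (log2 -0.73, edgeR adjusted p = 0.00237). Of 23 genes of LXR and lipid handling 1 rose and 4 fell (2 and 6 when adjusted over the list alone, median -0.09, camera adjusted p = 0.0516), with the cholesterol exporter gene Abca1 at -0.93 (edgeR adjusted p = 0.00953). Of 15 macrophage identity genes 1 rose and 1 fell (2 and 4 when adjusted over the list alone, median 0.05, camera adjusted p = 0.819), namely the fractalkine receptor gene Cx3cr1 (0.84) and Ms4a7 (-0.67).

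Beside the genes above, 4 lists of markers of other cells passed camera downward on fibronectin under IgG. Mast cell and basophil markers had a median of -0.82, with 2 of 8 called lower (3 when adjusted over the list alone, camera adjusted p = 4.49e-06), and this call held with an estimated correlation (adjusted p = 0.022); Prss34 fell by 0.80 on the log2 scale. Of 16 neutrophil markers 1 fell, the receptor gene Csf3r (log2 -0.73), as it also did when adjusted over the list alone (median -0.24, camera adjusted p = 0.000783), with an adjusted p = 0.0704 with an estimated correlation. Of 11 fibroblast and stroma markers 2 fell, also when adjusted over the list alone (median -0.53, camera adjusted p = 0.00104), with an adjusted p = 0.0704 with an estimated correlation. These were Col3a1 (-2.42) and Col1a2 (-0.83), calls lost without uncoated_IgG 1 or fibronectin_IgG 3 and without uncoated_IgG 1 or 2 or fibronectin_IgG 4 (edgeR adjusted p = 0.0503 to 0.0601 and 0.0577 to 0.0686). Of 7 B lymphocyte markers 1 fell, the immunoglobulin gene Ighm (log2 -0.88; 2 when adjusted over the list alone, median -0.59, camera adjusted p = 0.00295), with an adjusted p = 0.0578 with an estimated correlation.

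The effect of fibronectin was measured again under anti-ITGAV, with separate libraries on both coatings. Here 876 genes differed, 439 higher and 437 lower, of which 120 changed by at least 2-fold (70 up, 50 down; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Ccl2 rose to 155 ± 25.6 from 36.5 ± 3.66 CPM (SD, n = 4), a log2 change of 2.09 ± 0.17 (SE, edgeR adjusted p = 5.52e-06), and Ccl7, Ch25h, Epha2, Slco4a1 and Id1 rose by 2.19, 2.53, 2.49, 2.07 and 1.86. Cd4 fell to 0.883 ± 0.167 from 3.89 ± 0.652 CPM, a log2 change of -2.13 ± 0.20 (SE, edgeR adjusted p = 1.97e-05), and Prg2, Nrg2, Gpr162, Gprc5c and Samd4 fell by 1.94, 1.90, 1.76, 1.59 and 1.48 on the log2 scale. Itgav rose to 171 ± 13.9 from 95.7 ± 14.7 CPM, a log2 change of 0.84 ± 0.16 (SE, edgeR adjusted p = 0.0056), one of 3 integrin genes that rose, with Itgax (1.11) and Itga8 (0.86). The integrin list of 18 (3 higher and 2 lower when adjusted over the list alone, median 0.11) did not pass as a group (camera adjusted p = 0.071), and Itgb3 had a log2 change of -0.69 (edgeR adjusted p = 0.0812). Fn1 rose by 0.40 ± 0.11 (SE, edgeR adjusted p = 0.0492). Its call ended when any 1 of the 4 uncoated_antiITGAV libraries or fibronectin_antiITGAV 1, 2 or 4 was left out (adjusted p = 0.0653 to 0.145), and that of Itga8 without uncoated_antiITGAV 1 or 2 or fibronectin_antiITGAV 3 (adjusted p = 0.0536 to 0.0614). Leaving out uncoated_antiITGAV 1, 2 or 3 or fibronectin_antiITGAV 4 left 530, 428, 454 and 578 genes, and 972 were called without fibronectin_antiITGAV 3, of which 718 were among the 876.

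Of the lists of markers of other cells, 5 passed camera downward on fibronectin under anti-ITGAV, and 4 of these held with an estimated correlation. Of 16 neutrophil markers 8 fell (11 when adjusted over the list alone, median -0.50, camera adjusted p = 3.14e-09), among them Csf3r (-0.79), the myeloperoxidase gene Mpo (-0.74), Lcn2 (-0.58) and Ltf (-0.55), with an adjusted p = 0.0162 with an estimated correlation. Of 7 B lymphocyte markers 2 fell (3 when adjusted over the list alone, median -0.73, camera adjusted p = 0.00102), Ighm (-1.14) and Cd79a (-1.52), the latter not called without uncoated_antiITGAV 2 (edgeR adjusted p = 0.056). Of 8 mast cell and basophil markers 2 fell (3 when adjusted over the list alone, median -0.58, camera adjusted p = 0.00117), among them Prss34 (-1.32), and of 3 T and NK lymphocyte markers Cd4 alone fell, also when adjusted over the list alone (median -0.50, camera adjusted p = 0.00178). These 3 were the tested members of a list of 14, so the call is weak ground for a change in lymphocytes. The B lymphocyte, mast cell and lymphocyte lists each had an adjusted p = 0.0297 with an estimated correlation. Of 11 fibroblast markers 1 fell, Col1a2 (-0.99), also when adjusted over the list alone (median -0.68, camera adjusted p = 0.0129), with an adjusted p = 0.2 with an estimated correlation. The list's call ended without uncoated_antiITGAV 1 or fibronectin_antiITGAV 2 (camera adjusted p = 0.0569 and 0.053).

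On fibronectin under anti-ITGAV the lipid handling and Fcγ receptor lists passed camera downward, and the NF-kB, protease, immediate early and TGF-β lists upward. None of these 6 held with an estimated correlation, and most members did not pass singly. Of 23 genes of LXR and lipid handling 6 fell (7 when adjusted over the list alone, median -0.23, camera adjusted p = 0.00178), among them Abcg1 (-0.71), Pltp (-0.83) and Mylip (-0.41), with an adjusted p = 0.2 with an estimated correlation. Of 13 Fcγ receptor and signalling genes 3 fell (5 when adjusted over the list alone, median -0.08, camera adjusted p = 0.00978), among them the inhibitory receptor gene Fcgr2b (-0.55) and Fcgrt (-0.82), with an adjusted p = 0.264 with an estimated correlation. Of 26 NF-kB targets 6 rose and 2 fell (6 and 3 when adjusted over the list alone, median 0.14, camera adjusted p = 0.00178), with Tnfaip3 at 0.61 and Ccl4 at 0.89, and an adjusted p = 0.224 with an estimated correlation. Of 21 proteases and inhibitors 5 rose and 1 fell (6 and 2 when adjusted over the list alone, median 0.08, camera adjusted p = 0.0129), with Plau at 1.36, Mmp12 at 1.20 and Plaur at 0.90, and an adjusted p = 0.0627 with an estimated correlation. The list's call ended without fibronectin_antiITGAV 2 (camera adjusted p = 0.0501). Of 27 immediate early genes 6 rose and 1 fell (8 and 1 when adjusted over the list alone, median 0.09, camera adjusted p = 0.00537), with an adjusted p = 0.264 with an estimated correlation. Of 28 TGF-β genes 5 rose and 1 fell (7 and 1 when adjusted over the list alone, median 0.13, camera adjusted p = 0.0178), with Id2 at 1.00 and Bhlhe40 at 0.56, and an adjusted p = 0.224 with an estimated correlation. This list's call ended without uncoated_antiITGAV 4 or fibronectin_antiITGAV 2 (camera adjusted p = 0.0948 and 0.0533). Of 22 alternative activation genes 1 rose and 3 fell (2 and 4 when adjusted over the list alone, median -0.07, camera adjusted p = 0.322), with Arg1 at 1.16 and Clec10a at -0.99.

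Of 28 extracellular matrix genes 2 rose and 2 fell on fibronectin under anti-ITGAV (4 and 6 when adjusted over the list alone). The list's median was -0.21 (camera adjusted p = 0.0274), with an adjusted p = 0.264 with an estimated correlation. Its call ended without uncoated_antiITGAV 1 or fibronectin_antiITGAV 2 or 3 (camera adjusted p = 0.053 to 0.0822). The osteopontin gene Spp1 rose to 3115 ± 546 from 1661 ± 305 CPM (SD, n = 4, log2 0.91) and Thbs1 fell to 124 ± 20.5 from 319 ± 4.73 CPM (log2 -1.36). MHC class II genes, none of them called singly over all genes or adjusted over the list alone, stood lower (12 genes, median -0.36, camera adjusted p = 0.00755), with an adjusted p = 0.189 with an estimated correlation. Of 28 lysosome genes 2 fell, Lgmn (-0.38) and Hexa (-0.44), also when adjusted over the list alone (median -0.14, camera adjusted p = 0.0204), with an adjusted p = 0.448 with an estimated correlation. The list's call ended without uncoated_antiITGAV 1 (camera adjusted p = 0.0605). Each of these 2 genes lost its call when single libraries were left out (edgeR adjusted p = 0.0532 to 0.0614 for Lgmn without uncoated_antiITGAV 1, 2 or 3 or fibronectin_antiITGAV 1 or 4, and 0.0578 to 0.0604 for Hexa without uncoated_antiITGAV 1, 2 or 3). Glycolysis and hypoxia genes stood higher (26 genes, 2 rose, 4 higher and 2 lower when adjusted over the list alone, median 0.16, camera adjusted p = 0.0188), with an adjusted p = 0.457 with an estimated correlation. Unfolded protein response genes stood higher (16 genes, none called over all genes, 2 higher when adjusted over the list alone, median 0.20, camera adjusted p = 0.041), with an adjusted p = 0.356 with an estimated correlation. The glycolysis call ended without uncoated_antiITGAV 4 or fibronectin_antiITGAV 2 or 4 (camera adjusted p = 0.0928 to 0.135), and that of the unfolded protein response without uncoated_antiITGAV 2 or 4 or fibronectin_antiITGAV 2, 3 or 4 (0.0508 to 0.147). Beside these lists, mitochondrial transcripts stood higher (12 genes, median 0.50, camera adjusted p = 0.0263) and ribosomal protein genes lower (26 genes, median -0.23, camera adjusted p = 0.00189), with an adjusted p = 0.52 and an adjusted p = 0.445 with an estimated correlation. The mitochondrial median was -0.03 without fibronectin_antiITGAV 3 (camera adjusted p = 0.358) and -0.08 with each library's GC trend taken out.

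**Figure D4:**
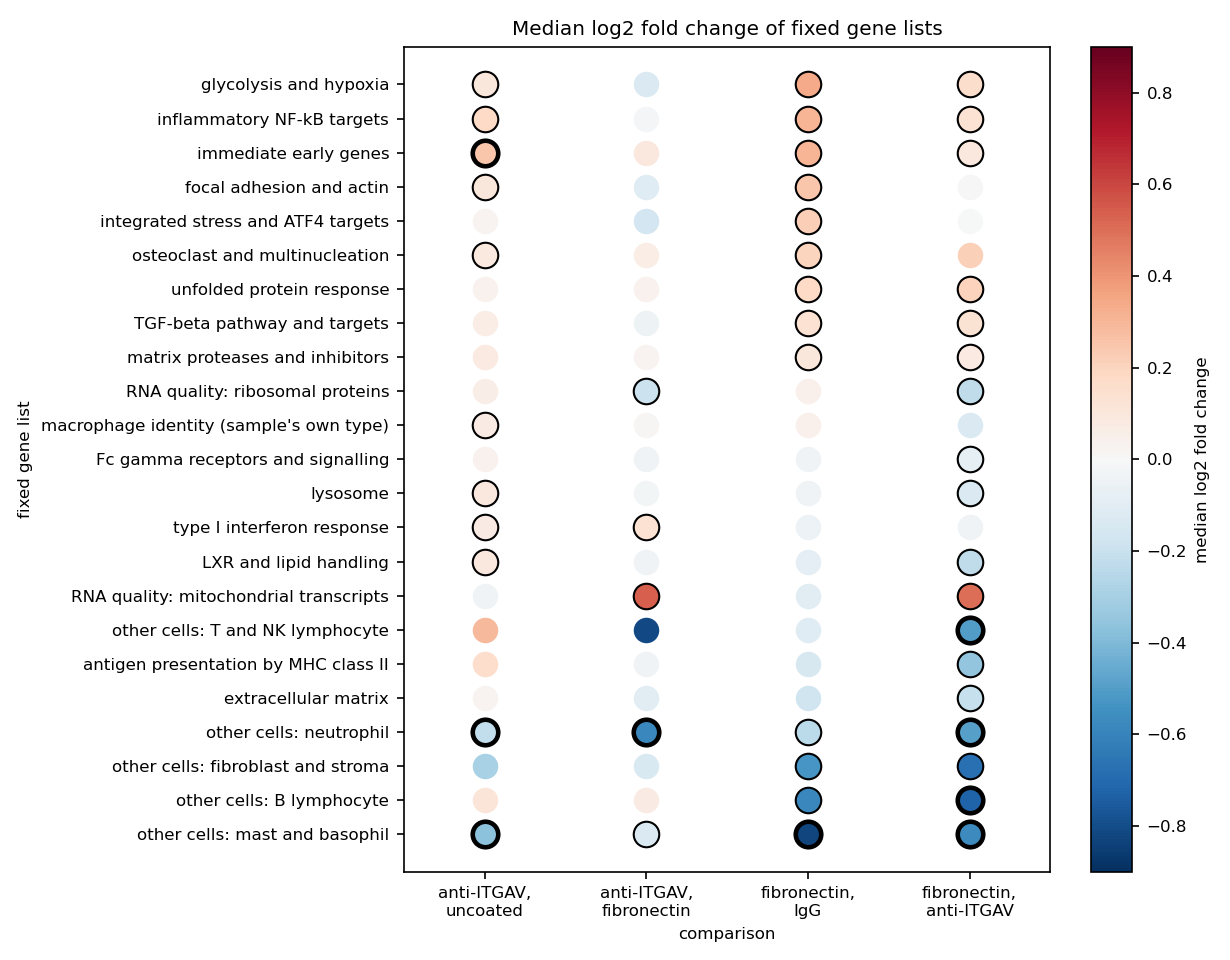
Median log2 change (colour, red higher and blue lower) of each fixed gene list that passed camera in at least 1 of the 4 comparisons of a pair of groups, with 1 column per comparison. A thin edge marks a camera adjusted p under 0.05, a thick edge a call that also held with an estimated correlation, and no edge a list that did not pass.

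The fibronectin effect was shared between the antibodies. Both comparisons called 189 genes higher, where 10.4 would overlap between independent lists of these sizes, and 141 lower, where 6.19 would. Of the 586 genes called under IgG, 579 had the same sign under anti-ITGAV and none was called with the opposite sign. Across those 586 genes the log2 changes had a Pearson correlation of 0.905 and a slope of 0.754, against a correlation of 0.317 over all tested genes, values across genes that are not independent replicates. The genes were chosen by their change under IgG, which by itself lowers the slope, so it does not show a weaker response under anti-ITGAV. Of the 24 genes that the naming rule gave by size of change for fibronectin under IgG, 20 were also called under anti-ITGAV. The 4 that were not, Il4, Gria3, Gpr34 and Map1a, had log2 changes of -0.62, -0.11, -0.76 and 0.74 there, and an edgeR adjusted p of 0.646 for the interaction.

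A last comparison asked whether αV neutralization on fibronectin ran against the effect of fibronectin. With the fibronectin_IgG libraries split, so that each effect used its own 2 of the 4, the Pearson correlation across genes was 0.0217 on average, with a range of -0.067 to 0.19 over the splits, and the covariance was 0.00503. With the same fibronectin_IgG libraries in both effects the correlation was -0.351 and the covariance -0.0431. In 10 simulations of unchanged groups that share those libraries the correlation was -0.5 and the covariance -0.044 ± 0.00144 (SD over simulations). Each gene was simulated independently, without the trends that genes share in the real libraries, so this SD may understate the spread. Ccl2 and Ch25h, which rose with fibronectin under IgG, had log2 changes of 0.14 and 0.13 for anti-ITGAV on fibronectin (edgeR adjusted p = 0.774 and 0.861).

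Of the 36 lists tested, 13 passed camera in none of the 4 comparisons of a pair of groups. These were integrin subunits, SRF and YAP targets, alternative activation, apoptotic cell uptake and scavenger receptors, cholesterol synthesis, oxidative phosphorylation, NRF2 and iron, proliferation, growth and angiogenic factors, and the markers of monocytes, dendritic cells, megakaryocytes and platelets, and endothelial cells. Their medians ranged from -0.41 to 0.39 and their smallest camera adjusted p was 0.0692, for growth and angiogenic factors under anti-ITGAV. The erythroid list had 2 tested genes and was not tested. Genes with near-identical copies, such as members of the chemokine, immunoglobulin and Fcγ receptor families, can share reads, and genes that overlap on opposite strands cannot be told apart where counting ignores strand; whether strand was used is not given in the sources used here.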

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

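Tests of gene length in the library that stood apart, of the neutrophil markers without that library and for a common factor, of the lists' interaction with 1 library left out or with the GC offset, of the split with 415 genes with that offset, and all tests on the fibronectin genes apart from the splits were chosen after the results were seen. In groups of 4, Dixon's test asks whether the highest or lowest library lies far from the others. It was run on 84 sets of values, where chance alone would pick about 1 in 20, or 4.2, and it picked 8. Itgb5 stood at 199 CPM in fibronectin_antiITGAV 3, against 308 to 325 CPM in the other libraries of its group. Ltf stood at 61.1 CPM in uncoated_IgG 3, against 67.1 to 68.3 CPM. Spic stood at 2.53 CPM in uncoated_antiITGAV 1, against 2.89 to 2.92 CPM. The total of fibronectin_antiITGAV 4 was 28.5 M counts, against 36.5 to 37.7 M. The mitochondrial share was 3.67% in fibronectin_antiITGAV 3, against 1.35 to 1.45%. Mean correlation with the other libraries was 0.976 in fibronectin_IgG 2, against 0.981 to 0.982, and 0.965 in fibronectin_antiITGAV 3, against 0.981 to 0.983. Spearman's rho of log2 deviation with gene length, across genes, was -0.223 in uncoated_IgG 4, against 0.0771 to 0.139.

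The antibody's effect on 7 gene lists differed between the coatings in a camera test of the interaction. The mean rho with GC content was higher with the antibody on uncoated dishes (0.25 against -0.07) and lower on fibronectin (-0.14 against 0.12). A GC trend could therefore add to such differences. The result with the GC offset is given here for mitochondrial transcripts only, so for the other lists GC bias stays open. The median interaction was -0.23 for focal adhesion and actin genes and -0.23 for glycolysis and hypoxia genes (camera adjusted p = 0.00202 each). It was -0.24 for immediate early genes (0.0466), -0.38 for neutrophil markers (0.00331) and -0.83 for the 3 T and NK lymphocyte markers tested (0.0495), where the median gene was Cd4. It was 0.59 for mitochondrial transcripts (0.00202) and -0.26 for ribosomal protein genes (0.00016). Without fibronectin_antiITGAV 3 the call for mitochondrial transcripts ended (median 0.00337, camera adjusted p = 0.522), as it did with the GC offset (median -0.17, camera adjusted p = 0.393), and the medians were -0.14 for focal adhesion and actin genes and -0.17 for ribosomal protein genes. The call for immediate early genes ended without uncoated_IgG 2 or 4, uncoated_antiITGAV 1 or 3, fibronectin_IgG 4 or fibronectin_antiITGAV 2 or 3 (camera adjusted p = 0.0502 to 0.176). That for T and NK lymphocyte markers ended without any 1 of the 16 libraries except uncoated_IgG 3 and fibronectin_antiITGAV 3 (camera adjusted p = 0.0512 to 0.403). None held with an estimated correlation, with an adjusted p = 0.442 for the neutrophil and lymphocyte markers and 0.734 for the others.

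The library fibronectin_antiITGAV 3 stood apart. Its GC trend was not the whole cause, since its mean correlation with the others rose from 0.965 to 0.978 when every library's trend was removed, still below the 0.980 to 0.985 of the others. Its rho with gene length was 0.127, within the -0.285 to 0.214 of the other libraries. This does not exclude a loss of long transcripts, since the GC trend was not removed and could mask it. Among the other libraries a high rho with GC content went with a low rho with length, as in fibronectin_IgG 2 (0.609 and -0.285). The reverse held in fibronectin_IgG 4 (-0.267 and 0.214). An uncoated dish was excluded by a fibronectin score of 0.378 in fibronectin_antiITGAV 3, against -1.01 to -0.402 in the uncoated libraries. More cells of another type stay open: 0 of 9 marker lists were highest in it, but all 9 lay within the range of the others, with megakaryocyte markers at 2.68 against up to 2.69 log2 CPM, and further types were not examined. What set this library apart stays open, and the design gave no biological explanation to test.

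Neutrophil markers such as Ltf, Lcn2, Camp and S100a9 stood lower with anti-ITGAV on both coatings. For the fall on fibronectin, GC bias as the whole cause was excluded by a camera adjusted p of 5.45e-26 with the GC offset (median -0.50). There fibronectin_antiITGAV 3 as the whole cause was excluded by a camera adjusted p of 1.2e-41 without that library (median -0.53). GC bias was not weighed in this way for the smaller fall on uncoated dishes. The 16 markers did not fall by 1 common factor, with a Cochran's Q of 103 against a 95% point of 25.0. This does not exclude a loss of neutrophils, since RNA of the same genes from other cells would make the falls unequal. The test also takes the genes' errors as independent. Mast cell and basophil markers stood lower on uncoated dishes (median -0.37, camera adjusted p = 0.000509, and adjusted p = 0.0368 with an estimated correlation), while on fibronectin 4 of the 8 were higher and 4 lower (median -0.13, camera adjusted p = 0.0372, 0.0585 to 0.332 without fibronectin_IgG 1 or 3 or fibronectin_antiITGAV 2 or 4, and adjusted p = 0.426 with an estimated correlation). A loss of neutrophils, a loss of some cells, such as those of 1 maturation stage, and an effect of the antibody on expression stay open, as no test told them apart.

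Fibronectin moved 586 genes under IgG. GC bias was excluded as the whole cause, since 571 (97.4%) stayed called with the same sign under the GC offset. An ongoing response to endotoxin in the coating could raise interferon genes with NF-kB targets, and the means were -0.13 and 0.40. The lists differed (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). This argues only against a response that raises both lists. A response that raises NF-kB targets alone and a past response that had waned stay open. Macrophage identity genes moved in both directions (Cx3cr1 0.84, Ms4a7 -0.67), with a median log2 change of 0.0463, against 0.60 in the genes that rose. This excluded a larger share of macrophages only as the whole cause of the rises. For the genes that fell it stays open, since 4 of 9 marker lists of other cells were lower in camera (medians of -0.82 for mast cells and basophils, -0.59 for B lymphocytes, -0.53 for fibroblasts and -0.24 for neutrophils), of which the first held with an estimated correlation (adjusted p = 0.022) and the others did not (adjusted p = 0.0578, 0.0704 and 0.0704), and a response of the macrophages was not tested apart from it.

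Other splits of the same libraries bore on each count. For 4 counts, 1 of 35 splits, the real one, was as high. They were the genes called for anti-ITGAV on fibronectin (2, highest other split 1), for fibronectin under IgG (586, highest other 0) and under anti-ITGAV (876, highest other 17), and the lists under anti-ITGAV (18, highest other 14). This share, 0.0286, is the smallest that 35 splits allow and was not adjusted over the counts, so it does not exclude chance by itself. The margin was wide for the genes changed by fibronectin. It was narrow for anti-ITGAV on fibronectin, where the libraries of the comparison fitted alone gave 0 genes. Chance was not excluded either for the genes called for anti-ITGAV on uncoated dishes (2, highest other 415, 2 of 35 splits as high). The split with 415 genes points to a structure of the samples: it set uncoated_IgG 1, 2 and 3 and uncoated_antiITGAV 4, with a rho with GC content of -0.353 to -0.156, against the other 4 libraries, at 0.214 to 0.605. Its difference in mean rho was the largest of the 35 splits (0.684, against 0.327 in the real one). With the GC offset it called 798 genes, so the trend that this offset removes was not the whole cause. This split differs from the real grouping only in uncoated_IgG 4 and uncoated_antiITGAV 4, which change sides. The structure is therefore partly confounded with the antibody on uncoated dishes. Other causes, such as an exchange of the labels of these libraries, were not tested. Chance was not excluded for the lists of that comparison (11, highest other 11, 2 of 35), of anti-ITGAV on fibronectin (5, highest other 8, 17 of 35) or of fibronectin under IgG (13, highest other 17, 5 of 35). For the interaction edgeR called 0 genes in all 100 splits drawn, the real one included, where 614 genes had an unadjusted p under 0.05 in the real split and DESeq2 called 1.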

How the results depend on the processing

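Voom weights, the GC offset and fits without fibronectin_antiITGAV 3 where it was not compared were chosen after the data were seen. Counts of genes are given in the order anti-ITGAV on uncoated dishes, anti-ITGAV on fibronectin, fibronectin under IgG and fibronectin under anti-ITGAV, which were 2, 2, 586 and 876; the cause was not tested unless stated. DESeq2 called 16, 16, 975 and 1509, and 1 for the interaction, and a test against 1.5-fold called 0, 0, 15 and 20 by its stricter null (88 and 94 genes at an unadjusted p under 0.05 for the 0 counts). Limma on log2(FPKM + 1) without a filter called 1, 4, 309 and 510, voom weights 109, 6, 2481 and 2173, and the GC offset 7, 9, 1718 and 1941. The GC offset without fibronectin_antiITGAV 3 called 24, 9, 2372 and 1989. No filter gave 4 genes for anti-ITGAV on fibronectin. The libraries of a comparison alone gave edgeR counts of 0 (276 at an unadjusted p under 0.05) for anti-ITGAV on fibronectin and 251 for fibronectin under anti-ITGAV, which both hold fibronectin_antiITGAV 3, and 3 and 831 for the others. Leaving out 1 library gave 0 to 2, 1 to 5, 253 to 1325 and 428 to 990 genes, and 0 to 0 for the interaction. For lists (11, 5, 13 and 18) it gave 9 to 13, 3 to 7, 13 to 18 and 12 to 19. An estimated correlation left 3, 1, 1 and 4 lists, fry left 3 and 1 for the antibody, and the GC offset gave 20 for fibronectin under IgG.

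The correlation of the antibody's effects between the coatings (-0.0509) was -0.00666 with DESeq2, -0.00598 without a filter, -0.19 at 1 CPM in 4 libraries and -0.128 with the libraries of a comparison alone. It was -0.309, -0.226 and -0.222 with limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 1) without a filter, 0.136 with voom weights, 0.0626 with the GC offset, 0.0507 with that offset and without fibronectin_antiITGAV 3, and -0.106 to 0.0329 with 1 library left out. The comparison of the antibody's effect with that of fibronectin (0.0217) was -0.351 unsplit, where shared libraries lower it, 0.0478 with the GC offset and -0.0156 to 0.0508 with 1 library left out. Mitochondrial transcripts reversed: for anti-ITGAV on fibronectin their median was -0.0134 to 0.696 with 1 library left out, negative without fibronectin_antiITGAV 3, and -0.138 with the GC offset and without that library. For fibronectin under anti-ITGAV it was -0.0343 to 0.649 with 1 library left out, negative without the same library, -0.335 with the GC offset as well and -0.0822 with the GC offset alone. No called named gene reversed in any setting; 29 of 46 values for anti-ITGAV on uncoated dishes, 39 of 44 on fibronectin, 1355 of 1562 for fibronectin under IgG and 1095 of 1239 under anti-ITGAV stayed past the threshold.

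With the replicate number as a block edgeR called 0 genes for anti-ITGAV on uncoated dishes (398 at an unadjusted p under 0.05) and 360 for fibronectin under IgG. The deviations of libraries that share a number had correlations of -0.301 to 0.277 over 24 pairs (median -0.0235), 4 of them over 0.1. In 2 of the 24 pairs the library of the same number was the best match. This check gave no sign of pairing. The GC trend was left in, which could hide one, so a pairing by number is not excluded.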

Other observations

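The set of genes described here, and its test, were chosen after the data were seen. With each library's GC trend taken out and without fibronectin_antiITGAV 3, edgeR's quasi-likelihood test called 24 genes for anti-ITGAV on uncoated dishes, 21 higher and 3 lower (Benjamini-Hochberg adjusted p under 0.05). Beside Myo1e and Fos, the lipoprotein lipase gene Lpl had a log2 change of 0.53 (edgeR adjusted p = 0.000507), Cytip 0.74 (0.000991), the endotoxin co-receptor gene Cd14 0.40 (0.00159) and the stress-induced transcription factor gene Atf3 0.34 (0.00178). The neutrophil granule gene Ngp stood at -0.56 (edgeR adjusted p = 0.00159), with Ltf and Lcn2 also lower. On fibronectin the same fit gave log2 changes of 0.34 for Lpl, 0.49 for Cytip, 0.28 for Cd14 and 0.26 for Atf3, of which none passed (edgeR adjusted p = 0.0615, 0.104, 0.104 and 0.0703), and -1.001 for Ngp, which did (8.39e-06).

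A hypothesis is that anti-ITGAV may move the same genes on fibronectin, in libraries whose group means took no part in choosing them. All 24 had the same sign there in this fit (22 of 24 without the GC correction and with all libraries), and 5 were also called, Myo1e, Fos, Ngp, Ltf and Lcn2. Over all 8 fibronectin libraries, fibronectin_antiITGAV 3 included, and with each library's GC trend removed, their mean log2 change counted in the direction seen on uncoated dishes was 0.337. Of 70 signed splits of these libraries 1, the real one, gave a mean as high, and the next gave 0.202 (exact permutation p = 0.0143, one-sided). Ltf and Lcn2 had already been called on fibronectin in the main fit. With Ngp they had the largest changes there of the 24 in the fit above (-0.96, -0.78 and -1.001). The mean without these genes was not tested.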
